A study of Mus musculus with 3 samples.

How the data were processed

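Testes of at least 2 pups were pooled per preparation, digested with trypsin and sorted for reporter brightness, and cells were loaded on a droplet system with 3' v2 chemistry, about 8700 cells per library with up to 5000 expected, per the labels' protocols. Which pups went into which library is not given in the sources used here. The deposited matrices hold whole-number UMI counts per gene and cell barcode, made by the authors with Cell Ranger on the mm10 (GRCm38) build, with bcl2fastq and FastQC also named, per the submitters' processing notes. Their versions are not given in the sources used here. Each matrix listed 27998 genes and as many barcodes as the number of cells in the labels (5238, 4390 and 3466). A deposited count matrix of all 13094 cells summed to 176171330 UMIs, 93.8% of the 187874381 UMIs of the separate libraries, and was used only for that total. No row of the matrices was named for EGFP, so reporter RNA was not measured.

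Cells were kept with at least 500 genes detected and at most 20% of UMIs from mitochondrially encoded genes, which left 5182, 4313 and 3451 cells. Scrublet, run in scanpy 1.11.5 with an expected rate of 0.04, called 3, 10 and 75 doublets. Its 0.0579% in the bright library was under the 0.5% set as the sign of a failed run, so no cells were left out in any library. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9, resolution 0.5, seed 0) gave clusters over all libraries without integration. Clusters were named from 10 marker lists. A marker counted at 20 CPM or more and at 25% or more of its highest cluster. A name needed 3 markers and leading genes that did not go against it, but stroma- and Leydig-like clusters were exempt from the check of leading genes. These scoring details were set after the clusters were seen. Classes are rebuilt here and are called by likeness only.

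UMIs of germ-like cells were summed per library (82628796, 69653668 and 7299130 UMIs) and expressed as CPM with exact Poisson 95% intervals. The log2 ratio of bright over dim had an exact conditional binomial interval, and counts under 3 were set to 3. Members of 22 gene lists counted as measured at 10 CPM or more in either sorted library. A list median was set beside 10000 random lists of the same size matched on mean CPM, and its percentile describes these libraries and is no p-value. Shares of cells used cells thinned to 8500 UMIs, from the 10th percentile of the shallowest library, and exact Clopper-Pearson intervals. Niche genes were given in classes of at least 30 cells. The marker and gene lists, the rule for named genes and 15 alternative settings were fixed before the data were examined, and 3 alternatives were added afterwards. Genes were named by rule. These were 9 spermatogonial genes, the 12 largest ratios each way at 50 CPM or more with a UMI in at least 5% of cells, up to 4 members per list, and niche genes at 20 CPM or more. The 12 left out mitochondrial, ribosomal protein and haemoglobin genes, somatic markers and genes at least 2 times higher in non-germ cells. Not every gene the rule names is printed, and some are not reported here.

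The ratio, its interval and the size rule were tested on simulated data for the bright over dim comparison over 7935 genes. Changes of log2 0.70, 1 and 2 were called in the right direction for 100.0% of 63, 59 and 78 changed genes, and 0% of 7735 unchanged genes were called. The simulation held counting error and no difference between cells or between animals. Counting error is small against the 1.5-fold limit at this depth, so the simulation checks the calculation and not how reliable a call is. Coordinates come from GENCODE M21 on GRCm38, in which 27645 of the 27998 gene identifiers were found. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, R 4.3.3 and edgeR 4.0.16, the last for scaling factors of an alternative only. Intervals for list medians in the alternatives came from Poisson resampling of the members' counts.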

Results

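Single cells from the testes of mice at postnatal day 6 were profiled by droplet-based 3' RNA sequencing. The mice carried an Id4-EGFP reporter, a fluorescent protein whose brightness follows Id4, which encodes an inhibitor of DNA binding found in spermatogonial stem cells. One library held cells sorted as ID4-EGFP-bright, one held cells sorted as ID4-EGFP-dim, and one held unselected testis cells. The comparison of the sorted libraries asks how spermatogonia of high and low reporter level differ, and the unselected library shows the cells around them. The bright library held 5238 cells and 82990799 unique molecular identifiers (UMIs), the dim library 4390 cells and 70578957 UMIs, and the unselected library 3466 cells and 34304625 UMIs. Median depth was 15361, 15562 and 8210.5 UMIs per cell in that order. Each group had 1 library, so no difference between libraries has a replicate check or a significance test, and every interval covers counting error only. Genes were called higher or lower by size, at 1.5-fold or more with an interval that excluded equality.

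Germ-like cells made up 99.9% of the kept cells in the bright sort (5176 of 5182, exact 95% interval 99.7 to 99.96%) and 98.8% in the dim sort (4260 of 4313, 98.4 to 99.1%). In the unselected suspension they made up 9.48% (327 of 3451, 8.52 to 10.5%). Sertoli-like cells, the supporting cells of the seminiferous tubule, were the most numerous class there at 54.5% (1881 cells, 52.8 to 56.2%). Peritubular myoid-like cells, the contractile cells around the tubule, made up 16.5% (570 cells), and stroma- and Leydig-like cells of the interstitium 17.0% (587 cells). Smaller classes of the unselected library were lymphoid-like (16 cells), endothelial-like (13 cells) and macrophage-like (10 cells). A further 47 cells carried markers of both Sertoli and interstitial cells and stayed unnamed, and 45 of them were called doublets. The dim sort held 36 Sertoli-like and 11 macrophage-like cells. The bright sort held 5 Sertoli-like and 0 macrophage-like cells, and a count of 0 allows up to 3 of 5182 cells, a share of 0.0579%. The sort gates set the shares in the sorted libraries. Under a filter of at least 2000 genes and at most 5% mitochondrial UMIs the germ-like share of the unselected library was 0.417%, since that filter removed nearly all germ-like cells.

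Id4 itself was 5.26-fold higher in germ-like cells of the bright library, at 93.3 CPM (the UMIs of a gene scaled to all UMIs of the summed cells, 91.2 to 95.4) against 17.7 CPM (16.8 to 18.8) in the dim library. Its log2 ratio was 2.39 (2.31 to 2.48), and germ-like cells of the unselected library lay between at 64.0 CPM. Genes of the receptor for glial cell line-derived neurotrophic factor (GDNF), a self-renewal signal, followed the same order. Gfra1, which encodes the ligand-binding subunit, stood at 77.5 CPM in the bright library, 8.10 in the dim and 41.8 in the unselected, and Ret, the kinase subunit, at 85.0, 18.0 and 57.4 CPM. Etv5, a transcription factor downstream of GDNF, stood at 81.4, 12.4 and 53.02 CPM. Genes of later spermatogonia had the opposite order. Kit, the stem cell factor receptor of differentiating spermatogonia, was at 17.0 CPM in the bright, 58.9 in the dim and 35.3 in the unselected library, a log2 ratio of -1.79 (-1.88 to -1.71). Stra8, a retinoic acid-responsive gene, was at 170 CPM in the bright and 342 in the dim library, and Sohlh1, a differentiation factor, at 150 and 279 CPM. Neurog3, a progenitor transcription factor, and Rarg, a retinoic acid receptor, were 3.57-fold and 3.99-fold higher in the dim library. On the GRCm38 assembly, Id4 (ENSMUSG00000021379) lies on chromosome 13 from 48261228 to 48266026. Gfra1 (ENSMUSG00000025089) lies on chromosome 19 from 58235604 to 58455909, and Kit (ENSMUSG00000005672) on chromosome 5 from 75574916 to 75656722. All 3 are annotated as protein-coding genes. Germ-like cells of the bright library lay mostly in clusters 0 to 3 and those of the dim library in clusters 4 to 6, so values of the sorted libraries compare different parts of the class. Under the stricter cell filter, which left 63 bright and 126 dim cells, the log2 ratio was -0.12 for Stra8 (-0.37 to 0.11), -0.52 for Sohlh1 and -0.63 for Neurog3 (-2.70 to 1.04), and none of the 3 kept its call. Ret (5.08, 3.44 to 7.41) lay further out there. Etv5 was at 3.52 (2.65 to 4.50), an interval that held its reported log2 ratio of 2.71.

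**Figure D1:**
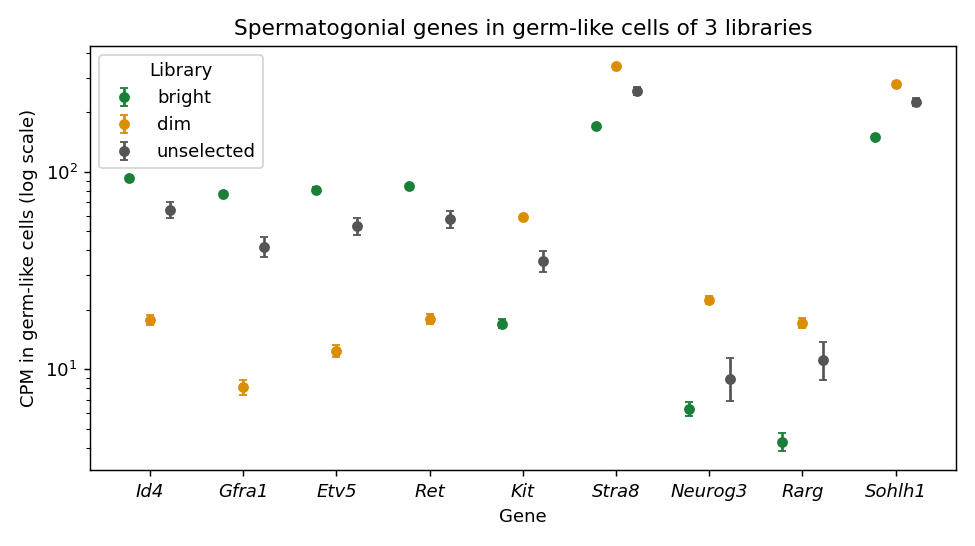
CPM of 9 spermatogonial genes (x axis) in the summed germ-like cells of the bright, dim and unselected libraries (log y axis), with exact 95% Poisson intervals that cover counting error only. Id4, Gfra1, Etv5 and Ret are highest in the bright library, the other 5 genes are highest in the dim library, and the unselected library lies between for all 9, as for Id4 at 93.3, 64.0 and 17.7 CPM.

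Stem-associated genes were higher in the bright library as a group. Of 9 measured members 8 were higher, 0 were lower, and the median log2 ratio was 2.39, above all 10000 random lists matched on expression. That median is the ratio of Id4, whose reporter set the sort gates, and the 8 members without Id4 had a median of 2.51, also above all random lists. Lhx1, a transcription factor gene, had a log2 ratio of 3.93 (46.0 against 3.01 CPM), and Egr2 one of 2.76 (36.6 against 5.41 CPM). Pan-undifferentiated genes went both ways, with 3 higher, 2 lower and 5 within 1.5-fold and a median of 0.32 (percentile 99.9). Itga6, an integrin subunit used to enrich spermatogonia, was 2.14-fold higher in the bright library, Pou5f1 was higher as well (log2 ratio 0.70), while Utf1 (-0.89) and Uchl1 (-0.70) were lower. Progenitor-associated genes had a median of -0.96, below all random lists, with 4 of 7 members lower and 0 higher. Sox3 was among them at 40.7 CPM in the bright and 85.1 CPM in the dim library. Differentiation-associated genes had a median of -1.05, also below all random lists, with 7 of 8 members lower and 0 higher. Dmrtb1, a regulator of the entry into meiosis, was at 5.05 CPM in the bright and 47.4 CPM in the dim library (log2 ratio -3.23), and Prss50 had a log2 ratio of -2.91. All 12 measured meiosis genes were within 1.5-fold (median -0.09). The progenitor-associated median was -0.51 over the 2 members at 50 CPM or more. Under the stricter cell filter it was 0.85, the pan-undifferentiated median was 1.27 and the stem-associated median 3.06, Utf1 turned direction (1.45, 0.34 to 2.58), Uchl1 (-0.45) lost its call and Pou5f1 was at 3.17 (2.31 to 4.13).

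Across all genes at 10 CPM or more in either sorted library (8321 genes), the median log2 ratio was -0.06. The genes ranked next had at least 50 CPM in the higher library, a UMI in at least 5% of its cells, and were not at least 2 times higher in non-germ cells. Among these and beside the genes above, the 12 with the largest ratio toward the bright library held Nefm, a neurofilament subunit (103.7 against 12.2 CPM, log2 ratio 3.08), and Tcl1, a coactivator of AKT (2.59). They also held Fst, which encodes the activin-binding protein follistatin (2.42), Upf3b of nonsense-mediated decay (2.39) and Rasgrp2, a guanine nucleotide exchange factor (1.95). Ccnd2, the D-type cyclin, was the most abundant of the 12 at 673 CPM in the bright and 190 CPM in the dim library (1.83). Toward the dim library the largest among them was Lmo1, a LIM-domain cofactor, at 19.2 against 111 CPM (log2 ratio -2.53, -2.61 to -2.45). Lmo1 (ENSMUSG00000036111) lies on chromosome 7 from 109138572 to 109175207. Retinoid-binding proteins were in this set as well, with Crabp1 at 89.9 against 289 CPM (-1.68) and Rbp4 at -1.45. The others included Eef2k (-1.69), Crip2 (-1.63), the mitophagy gene Bnip3 (-1.58), Nt5dc2 (-1.48) and the methylcytosine dioxygenase gene Tet3 (-1.46). Ccng1 (-1.43), Akt1 (-1.38) and Galnt12 (-1.34) completed it. Under the stricter cell filter Nefm (5.46), Tcl1 (3.73), Upf3b (3.42), Ccnd2 (2.97), Ccng1 (-2.82), Akt1 (-2.51), Nt5dc2 (-2.28) and Rbp4 (-2.11) lay further out. Fst was at 3.21 (2.23 to 4.31), an interval that held its reported value. Genes at least 2 times higher in non-germ cells were set apart. Of these, Cited1 was at 13.1 CPM in the bright and 117 CPM in the dim library (log2 ratio -3.16) against 448 CPM in non-germ cells. Smoc2 was at 65.4 and 15.8 CPM (2.05) against 201 CPM, and Cd63 at 37.2 and 121 CPM (-1.70) against 586 CPM. Summed Sertoli markers in germ-like cells were 27.4 CPM in the bright, 24.3 in the dim and 284 in the unselected library. Summed perivascular markers were 113, 43.6 and 95.2 CPM in that order, of which Mcam, named after its values were seen, made up 111, 40.9 and 93.4 CPM.

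Feedback genes of the ERK pathway, which growth factor receptors activate, were higher in the bright library in all 7 measured members, with a median log2 ratio of 1.64 above all random lists. Spry4 had a log2 ratio of 3.28, Dusp6, an ERK phosphatase, one of 2.73, Etv4 one of 1.87 and Spry1 one of 1.64. Immediate early genes had a median of 1.13, with 5 of 8 measured members higher and 0 lower. Ier3 (1.82), Egr1 (1.63), Ier2 (1.44) and Zfp36 (1.35) were the furthest, and Egr1 was also at 249.7 CPM in non-germ cells against 84.1 CPM in the bright library. Fos, Fosb, Jun, Junb and Atf3 were under 10 CPM in both sorted libraries and did not count as measured. Retinoic acid pathway genes had a median of -0.67 (percentile 0.17), with 3 of 5 measured members lower, among them Crabp1. Notch pathway genes split, with Notch1 (1.45), Hes1 (1.16) and Notch2 (0.87) higher and Dll3 (-1.41) and Hey1 (-1.04) lower (median 0.024). Members of the p53 target and apoptosis list split too. Pmaip1, a proapoptotic BH3-only gene, was higher (1.89), Phlda3 (-2.26) and Ccng1 were lower, and 7 were within 1.5-fold. Niche receptor genes had a median of 0.41, with Erbb3 (2.13) and Igf1r (0.61) higher and Acvr2b (-0.63) lower. Of the niche ligand genes 3 were measured in germ-like cells, with Igf2 at 1.32 and Pdgfa and Nrtn both at -0.87. The 3 measured ID and E-protein genes, Tcf3, Tcf4 and Tcf12, were within 1.5-fold (median -0.07), and Id1, Id2 and Id3 were under 10 CPM. Members at 1 CPM or more gave medians of -0.36 for retinoic acid and -0.15 for niche ligand genes, while at 50 CPM or more the retinoic acid list held 1 member, Crabp1, and the ERK feedback list 2, Dusp6 and Etv4 (median 2.30). Igf1r slipped just under 1.5-fold in thinned cells (0.575) and without cells under 10000 UMIs (0.584), as did Acvr2b with scaling by trimmed means (-0.58). Under the stricter cell filter Spry1 lost its call (-0.33, -1.96 to 1.08) and the Notch median was 0.90. Dusp6 (4.34), Egr1 (2.56), Igf1r (1.46), Phlda3 (-3.26) and Nrtn (-1.63) lay further out there. So did Ier3 (3.08, 1.43 to 5.13), Zfp36 (2.44, 0.83 to 4.29), Etv4 (2.52, 1.79 to 3.30) and Hey1 (-1.63, -3.61 to -0.12), but their intervals held the reported values.

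Most genes of both cell cycle lists were within 1.5-fold, though both medians leaned slightly toward the bright library. Ccnd2, which is in neither list, had a log2 ratio of 1.83. All 20 S phase genes were within 1.5-fold, with a median log2 ratio of 0.09 (percentile 97.8). Of 20 genes of G2 and M phase 3 were higher in the bright library and 17 were within 1.5-fold, with a median of 0.18 (percentile 99.8). The 3 were Nusap1 (0.89), the proliferation marker Mki67 (0.70, 92.1 against 56.7 CPM) and Top2a (0.68). All 24 nuclear genes of oxidative phosphorylation were within 1.5-fold (median -0.06). Glycolysis genes had a median of 0.25, with Ldhb (1.47) and Hk2 (0.88) higher and Eno1 (-0.62) lower. Mitochondrially encoded genes had a median of 0.06, with mt-Nd3 (0.81) and mt-Atp8 (0.78) higher. The cholesterol synthesis list had a median of 0.19, with Mvd lower (-0.61). DNA methylation genes had a median of -0.34, with Tet3 and Gadd45a (-0.65) lower. The piRNA pathway list had a median of -0.06, with Pld6 (-0.87) and Henmt1 (-0.73) lower. All 8 measured heat shock genes were within 1.5-fold (median 0.10). Scaling by trimmed means put Mvd at -0.57 and Eno1 at -0.57, just under the 1.5-fold limit. The stricter cell filter ended the calls of Nusap1 (0.58), Mki67 (0.53), Top2a (0.33), Hk2 (0.57), Eno1 (-0.40) and Henmt1 (-0.26), and put Ldhb further out (2.61). Except for Top2a (0.11 to 0.54), the intervals of the ended calls still held the reported values, so that filter left too few cells to tell.

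**Figure D2:**
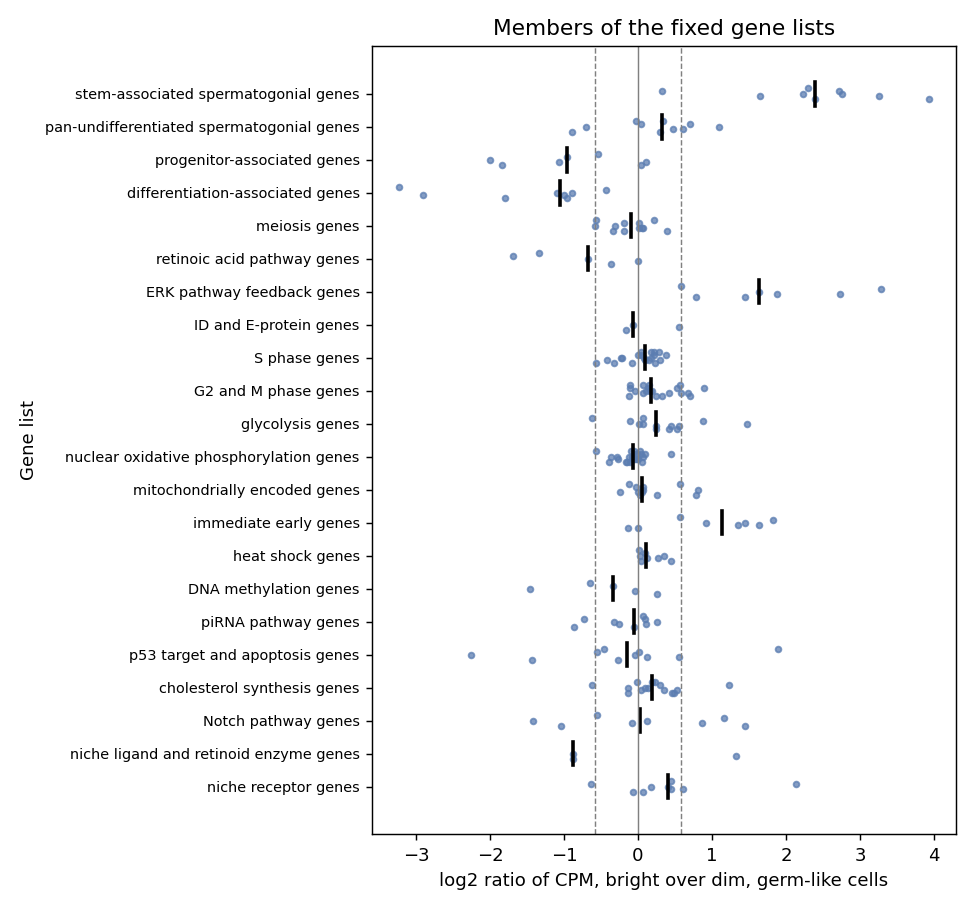
log2 ratio of CPM, bright over dim, in germ-like cells (x axis) for each measured member (points) of 22 gene lists (y axis), with each list's median as a black bar and 1.5-fold marked by dashed lines. Stem-associated genes have a median of 2.39 and ERK feedback genes one of 1.64, while progenitor-associated and differentiation-associated genes have medians of -0.96 and -1.05.

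Per cell, the detected UMIs of the sorts overlapped, and how much of that overlap comes from missed transcripts was not tested. With every cell thinned to 8500 UMIs, 10.1% of germ-like cells in the bright library had a Kit UMI (9.27 to 11.02%) against 33.6% in the dim (32.1 to 35.1%) and 21.7% in the unselected library (17.2 to 26.6%). The share in non-germ cells of the unselected library was 2.66%. Non-germ shares come from that library, and germ RNA in other cells was higher in the sorted ones, with summed germ markers in Sertoli-like cells at 584 CPM in the bright (5 cells), 145 CPM in the dim (36 cells) and 20.6 CPM in the unselected library. Without thinning, 2 of the 53 non-germ cells of the dim library (median 6923 UMIs) had a Kit UMI (3.77%, 0.460 to 13.0%) and 1 a Gfra1 UMI (1.89%, 0.0478 to 10.1%). These cells are too few and too shallow to tell how much of the Gfra1 share of dim germ-like cells is background. The bright library held only 6 non-germ cells. Thinning left out 512, 211 and 13 shallower germ-like cells and 1882 non-germ cells, and without it the shares were 17.1%, 46.1% and 32.7%. Id4 was detected in 48.0%, 12.1% and 35.4% of germ-like cells and in 3.78% of non-germ cells (62.4%, 19.2% and 49.2% of germ-like cells without thinning). Gfra1 was detected in 46.3%, 5.85% and 21.3%, against 0.483% of non-germ cells (62.5%, 9.34% and 41.0% without thinning). Etv5 was detected in 47.4% of bright cells, 8.50% of dim cells and 9.18% of non-germ cells. Non-germ cells held Etv5 at 14.3 CPM, so their share is no measure of free RNA. Without thinning the Etv5 shares were 64.8% and 13.2%. Neurog3 was detected in 3.47%, 13.0% and 6.37%, and Mki67 in 47.5%, 33.9% and 38.5%, against 0% and 28.3% of non-germ cells, which themselves held Mki67 at 55.98 CPM. Without thinning the shares were 6.49%, 21.8% and 11.9% for Neurog3 and 62.5%, 49.8% and 63.3% for Mki67. Median depth before thinning was 15443, 15724 and 22023 UMIs in germ-like cells and 7954 in non-germ cells. A randomly drawn bright cell had more stem-associated UMIs than a randomly drawn dim cell in 84.2% of pairs, counting ties equally to both sides. The median was 5 such UMIs in bright and 1 in dim cells. Without Id4 the share of pairs was 82.7%. For differentiation-associated UMIs the bright cell was above in 23.0% of pairs, with medians of 3 and 7. Progenitor-associated UMIs separated the sorts less, with the bright cell above in 41.0% of pairs and medians of 1 and 2. In thinned cells Stra8 was detected in 38.2% of bright and 57.0% of dim cells, and Sohlh1 in 62.8% and 85.7%.

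In the unselected library, Sertoli-like cells held most transcripts of several niche factors. Gdnf was at 23.6 CPM there (21.3 to 25.9), against 11.6 in myoid-like cells, 6.52 in stroma- and Leydig-like cells and 0.411 in germ-like cells. Kitl, the ligand of KIT, was at 187 CPM in Sertoli-like cells (181 to 194) and at 30.4 CPM or less in the other 3 classes. Wnt6 (520 CPM), the inhibin subunits Inha (1613 CPM) and Inhbb (183 CPM), the hedgehog ligand Dhh (279 CPM), Pdgfa (184 CPM) and the retinoic acid-producing enzyme gene Aldh1a1 (581 CPM) were also highest there. Stroma- and Leydig-like cells were highest for Cxcl12, a chemokine that binds CXCR4 (829 CPM, 801 to 857), followed by myoid-like cells at 246 CPM. They were also highest for Igf1 (631 CPM), the activin subunit Inhba (545 CPM), Wnt5a (118 CPM), Tgfb2 (59.4 CPM) and Nrg1 (36.4 CPM). Myoid-like cells were highest for Bmp4 (27.8 CPM) and Fgf2 (25.8 CPM). They were also highest for Igf2 (77.8 CPM, 69.7 to 86.5). Its interval overlapped that of stroma- and Leydig-like cells (65.2 CPM, 57.6 to 73.4). Germ-like cells were highest for the receptor genes Igf1r (92.2 CPM) and Acvr2b (72.2 CPM) and for the ligand gene Nrtn (33.6 CPM). Of the 27 niche genes at 20 CPM or more in any class, the 3 highest in germ-like cells could not be compared under the stricter cell filter, which left too few of those cells. Of the other 24, 23 had the same highest class there, and Fgfr1, at 102 CPM in stroma- and Leydig-like and 101 CPM in myoid-like cells, was highest in the latter, as it was without called doublets and without cells under 10000 UMIs.

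**Figure D3:**
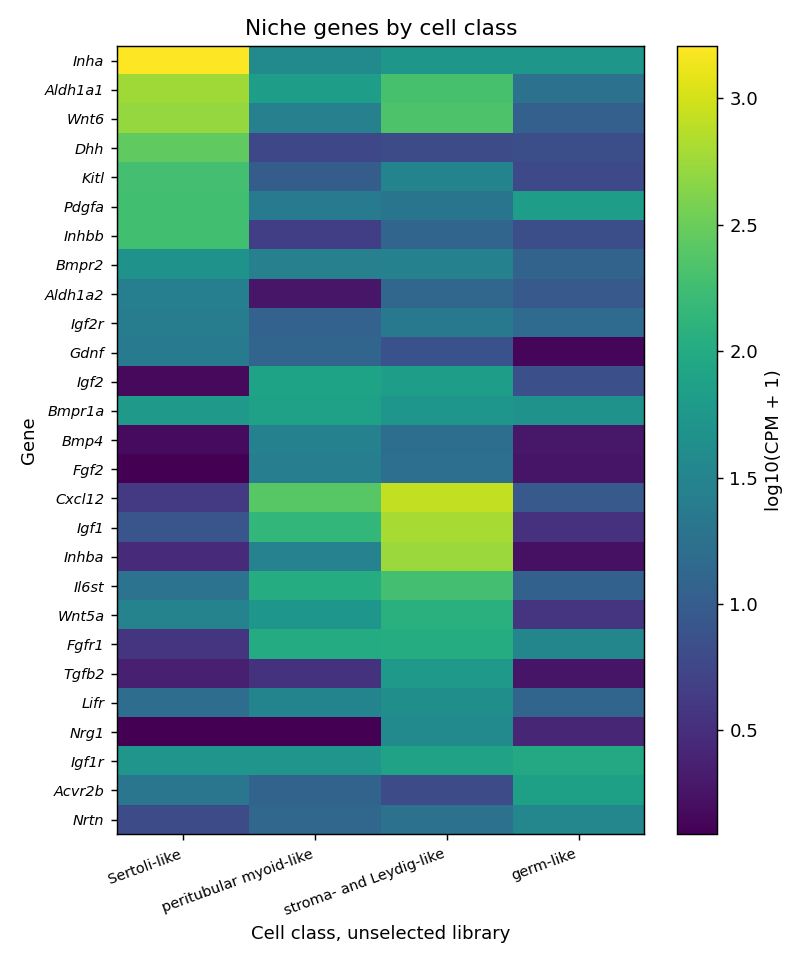
log10(CPM + 1) of 27 niche genes (y axis) in 4 cell classes of the unselected library (x axis), from dark (low) to light (high). Inha is at 1613 CPM in Sertoli-like cells and Cxcl12 at 829 CPM in stroma- and Leydig-like cells.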

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

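Leaving out cells under 10000 UMIs, called doublets or Id4 from the stem-associated list was chosen after seeing the data. No paired analysis was possible because each group has 1 library, and every value below is a value with no test. A value counts as moved when it left the counting interval of the reported value, which is narrow at this depth. Of the 71 named genes past 1.5-fold, all 71 kept their direction under each setting except the stricter cell filter, where 68 did, 59 stayed past 1.5-fold and 24 lay more than 1.5-fold further out. That filter (at least 2000 genes, at most 5% mitochondrial UMIs) left 63 bright and 126 dim cells, and few germ-like cells passed it. Intervals there were wide, and for some of the 24, such as Ier3 (1.43 to 5.13), they held the reported value. Under it the germ-like share was 100% in the bright, 88.1% in the dim and 0.417% in the unselected library, and Sertoli-like, myoid-like and stroma- and Leydig-like shares were 35.5%, 35.4% and 25.5%. Id4 had a log2 ratio of 2.95. The medians were 3.06 for stem-associated, 1.27 for pan-undifferentiated, -1.49 for differentiation-associated, -0.18 for S phase and 0.063 for G2 and M phase genes. The progenitor-associated median reversed to 0.85, and so did Utf1 (1.45) and Upp1 (1.103), while Spry1 lost its call at -0.33 (-1.96 to 1.08), and the cause was not tested. The share of cells with a Kit UMI was 7.89% in the bright (1.66 to 21.4%) and 31.3% in the dim library (22.4 to 41.4%). In the unselected library it was 0% (0 to 45.9%), from too few germ-like cells to show a drop. The stem-associated median was 2.51 without Id4. Members at 50 CPM or more gave -0.51 for progenitor-associated (2 members), -1.01 for differentiation-associated, 0.15 for S phase and 0.29 for G2 and M phase genes, and members at 1 CPM or more gave 0.41 for pan-undifferentiated genes. Scaling by trimmed means gave 0.39 for pan-undifferentiated, -1.01 for differentiation-associated, 0.14 for S phase and 0.23 for G2 and M phase genes, and shifted the median of all genes by 0.05. It took Mvd, Eno1 and Acvr2b just under 1.5-fold, as thinning and leaving out cells under 10000 UMIs did for Igf1r. Totals without mitochondrial and ribosomal protein genes gave 0.37 for pan-undifferentiated genes. Thinned cells gave 0.29 for pan-undifferentiated and -1.09 for differentiation-associated genes, and the mean of per-cell CPM gave -1.12 for the latter. Each library clustered alone gave a germ-like share of 100% in the bright library and a myoid-like share of 18.5%. Without thinning the Kit shares were 17.1%, 46.1% and 32.7% in the bright, dim and unselected libraries, and thinned to 4250 UMIs they were 6.46%, 20.9% and 13.5%, as depth sets detection. Leaving out cells under 10000 UMIs gave germ-like shares of 99.98%, 99.6% and 30.01% and Sertoli-like, myoid-like and stroma- and Leydig-like shares of 52.5%, 5.32% and 7.07%, since somatic cells were shallower. Ignoring doublet calls changed nothing, because no cells had been left out on them, and says nothing on stability. Leaving out the called doublets kept all 71 named genes past 1.5-fold. Of the other values under an alternative, 2152 stayed within their interval, 396 moved and 3 changed sign. The 3 were Utf1, Upp1 and Spry1, the last with an interval that includes equality. The 2152 include the values with doublet calls ignored, which could not change.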

Other observations

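Apart from the test of ERK signalling over the whole immediate early list, the values and tests in this part were chosen after the data were seen. Classes of the unselected library differed in proliferation genes. Summed S phase genes stood at 2452 CPM in germ-like, 1142 in Sertoli-like, 828 in myoid-like and 594 in stroma- and Leydig-like cells, and summed G2 and M phase genes at 2418, 1880, 890 and 698 CPM. Mki67 was at 67.1 CPM in germ-like and 64.5 CPM in Sertoli-like cells, with overlapping counting intervals, and at 30.6 CPM in stroma- and Leydig-like cells. Ccnd2 was highest in Sertoli-like cells (1056 CPM), and Cdkn1c, which encodes a cyclin-dependent kinase inhibitor, in stroma- and Leydig-like cells (263 CPM). Summed glycolysis genes were at 4825 CPM in Sertoli-like and 2702 CPM in germ-like cells, and summed cholesterol synthesis genes at 380 and 922 CPM.

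In germ-like cells thinned to 8500 UMIs, Id4 and Gfra1 occurred together more often than independent detection would give, in 25.7% of bright cells against 22.2% and in 1.85% of dim cells against 0.710%. Gfra1 and Kit occurred together less often, in 3.99% of bright cells (3.44 to 4.59%) against 4.69% and in 0.543% of dim cells (0.341 to 0.821%) against 1.97%.

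The dim library held 11 macrophage-like cells, the bright library 0 and the unselected library 10. They were 20.8% of the 53 non-germ cells of the dim library (10.8 to 34.1%) and 0.320% of the 3124 non-germ cells of the unselected library (0.154 to 0.588%), which argues against random carry-over of the suspension. Their germ marker level was 1.26% of that in germ-like cells, with an upper bound of 3.22%, which argues against doublets with germ cells. Autofluorescence of macrophages in the dim gate may bring them there, but no value here bears on it, and no biological explanation was tested.

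For the 5 immediate early genes higher in the bright library (Egr1, Ier2, Ier3, Zfp36 and Klf6), the somatic share of UMIs read from Sertoli markers was only 0.0409 percentage points higher in bright than in dim germ-like cells, while the genes would need at least 9.73%, which argues against free somatic RNA. Germ-like cells of the unselected library, which had not been sorted, stood above the dim library by a median log2 ratio of 0.85 with free RNA taken off. This cannot decide on passage through the sorter, since the dim cells were sorted too and the unselected cells mix both parts of the class. It also rests on 1 library, and the digestion was common to all. ERK signalling in the same cells may raise them. Within each library, cells with many ERK feedback UMIs were compared with cells with few. Many meant at least 3 UMIs and few at most 1 in the bright library, but at least 1 and 0 in the dim library. Ratios of the libraries are therefore unlike contrasts. The test over the whole list, set before its result was seen, used its measured members. Cells with many had 1.06 times the immediate early CPM in the bright library (1.03 to 1.09). In the dim library they had 1.101 times (1.07 to 1.13). Both values left the question undecided, and heat shock genes gave 1.04 and 1.02. Over the 5 genes alone, tested because the first test was undecided, the ratio was 1.63 (1.54 to 1.72) in the bright library. In the dim library it was 1.95 (1.79 to 2.13). In the bright library the 5 genes were at 229 against 140 CPM and the whole list at 676 against 636 CPM. The other measured members were thus together lower in bright cells with many ERK feedback UMIs. In the dim library, at 86.7 against 44.4 and 601 against 545 CPM, they were slightly higher. But the 5 genes and the ERK feedback genes both follow the bright to dim order. An order shared by many genes therefore stays open as an explanation, as does the reporter level itself.

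Germ-like cells under 10000 UMIs made up 14.8% of the bright library (765 cells) and had 3131 CPM of Actb against 1131 CPM in the deeper cells, while in the dim library they made up 8.33% and had 1420 against 771 CPM. Leakage of cytoplasm would leave a mitochondrial share of 19.7% in the bright library if mitochondria were kept, and the median was 9.43% against 8.64% in the deeper cells. The filter at 20% mitochondrial UMIs removes leaking cells, but over all germ-like barcodes the median was 9.68% in the bright library (819 cells) and 11.2% in the dim library (426 cells), under the midpoints of 14.4% and 13.5% toward leakage, which argues against leakage as the whole cause. The somatic share in these cells was 0.462% in the bright library, with an upper bound of 0.516%, and 0.410% in the dim, with one of 0.484%, while the excess of Actb would need 112% and 36.5%, which argues against somatic material. A small cell size or another cell state may remain: in the bright library 473 of these cells lay in cluster 3, led by Hsf2, Rpgrip1 and Slc39a1, whose deeper cells also held 3525 CPM of Actb, but Actb helped define that cluster, cells outside it still had 1528 against 949.8 CPM, and only 24 of the 355 in the dim library lay in it.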
